A study of Mus musculus with 17 samples.

How the data were processed

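Labelled RNA was hybridised to mouse arrays with 44397 spots each, of which 1377 were controls and 43020 carried 39429 probes. Per the labels, total RNA was extracted with Trizol and RNeasy columns, amplified with the WT-Ovation Pico system, which copies small amounts of RNA into cDNA, and labelled with Cy3 by the BioPrime Array CGH system. Per the file headers, spots were read with Agilent Feature Extraction 10.5.1.1, and the submitters' notes give version 9.53. The deposited intensity of each spot is the processed Cy3 signal of that program, after its background subtraction and with no scaling between arrays. The authors also deposited a table of their own comparisons. Per its column names, the deposited score of a probe is a signed fold change between group means, in which a ratio under 1 is written as minus its inverse, and a false discovery rate in percent stands beside it. The normalization and test behind that table are not given in the sources used here. It was used as an alternative only.

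The values were checked before use: no non-control spot was saturated on any array, the replicate spots of 399 probes with 10 spots each were averaged, and 135 probes with an outlier spot on at least 1 array were left out. The log2 of the deposited intensity minus the log2 of the 75th percentile of non-control probes of the array was the value of each probe. A probe was kept if it was well above background, by the flag of the extraction program, on at least 2 of the 17 arrays, which left 32302 probes. Gene names were updated with the mouse reference annotation (GRCm38.p6), which served for names only: 26412 probes were named through a transcript accession, 3854 by a current symbol and 735 by an older symbol, and 8428 kept the name in the files. Of several probes of a gene, the one with the highest mean stood for the gene, which gave 25975 genes of 31693 names. Of 5271 genes with several probes, the number with probes that passed in opposite directions was 24 for the hepatocyte condition against undifferentiated cells and 0 for the cholangiocyte condition. It was 245 and 8 for the conditions against their primary cells, 14 between the conditions, 160 between the primary cell types, and 243 and 7 for primary hepatocytes and primary cholangiocytes against undifferentiated cells. None of the genes named for a comparison is among these.

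Group means were fitted to all 17 arrays in 1 model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups share an estimate of the spread. The 8 comparisons and the difference of differences between lineages were contrasts of that model. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and the number with an absolute log2 difference of at least 1 (2-fold) is given too. All tests were two-sided. Unadjusted p under 0.05 were found for 7180 genes in the hepatocyte condition and 3326 in the cholangiocyte condition against undifferentiated cells. They were found for 16611 and 8054 genes against the primary cells, 7160 between the conditions, 14547 between the primary types, 17611 and 8093 for the primary types against undifferentiated cells, and 12216 for the difference of differences. The values were handled with the R package data.table, version 1.17.8, blocks and weights were fitted with statmod 1.5.0, and figures were drawn with matplotlib 3.10.9.

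A gene that was not well above background on any array of 1 group received a lower bound. Each array of that group was put at its dimmest value well above background, or at its own value if that was higher, and the fold to the mean of the other group is written as at least N-fold, with the adjusted p of the fit. Medians of lists were computed with fitted differences and again with such genes at their bounds.

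The comparisons, the test, the gene filter, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named 16 marker genes in any comparison, whether they passed or not. It named the 6 genes with the largest positive and the 6 with the largest negative differences per comparison, among those that passed, carry a gene symbol, were well above background on every array of both groups and did not overlap between them. It also named up to 4 members of each list per direction that passed, by size, and up to 2 that did not. The difference of differences had no genes named by size. The text gives a part of the genes the rule named, and some of the others are not reported here.

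The 21 lists held markers or pathway members: plasma proteins, cytochrome P450 and conjugation enzymes, urea cycle and amino acid breakdown, glucose and glycogen metabolism, bile acid synthesis and transport, fatty acid oxidation, complement, liver transcription factors, biliary markers, progenitor and fetal liver genes, cell cycle, Notch pathway, YAP targets, extracellular matrix, stellate cells, leukocytes and Kupffer cells, endothelial cells, red blood cells, cholesterol synthesis, interferon-stimulated genes, and immediate-early and heat shock genes. Each was tested against the other genes with camera at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the lists within a comparison. Members were counted with p adjusted over all genes and adjusted over the list alone.

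By the barcodes in the file names the arrays lay on 5 slides. Per the file headers each slide was scanned in a single session, and the labels number the replicates. Slide entered as a fixed or random block in alternatives, and differences were computed within each slide that held both groups. The genes counted as passing for a slide were called without the arrays of that slide. Deviations from the group mean were compared across genes between arrays of different groups. They correlated at a mean r of -0.002 over 28 pairs with the same replicate number, against 0.001 over 86 other pairs. The numbers were not taken to pair samples, although this mean over all groups cannot exclude pairing within some of them. Single arrays did match. Undifferentiated arrays 1 to 3 correlated at 0.385, 0.281 and 0.318 with cholangiocyte condition arrays 1 to 3. Undifferentiated arrays 1 to 4 correlated at 0.385, 0.442, 0.351 and 0.519 with hepatocyte condition arrays 3, 1, 2 and 4. The other pairs of undifferentiated arrays with either condition were at most 0.028. A match by source was not tested. The main fit did not use it, so any difference between sources entered the spread of that fit. Arrays on the same slide correlated at 0.067 over 22 pairs, against -0.016 over 92.

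The other alternatives, each changing 1 choice, were normexp background correction with an offset of 50, no filter on dim probes, a filter that asks for every array of at least 1 group, median scaling, quantile normalization, scaling by probes above background on all arrays, the mean of the probes of a gene, array weights, a trended and robust prior, a block by replicate number, a fit to the compared groups alone, and leaving out each array in turn. The authors' deposited table was matched to 25801 genes through 37908 probes, with 0 of its comparison columns unmatched. Log2 folds of the authors' deposited table correlated with the differences here at r = 0.975 to 0.995 across genes. At a false discovery rate of 5%, the authors' deposited table called 4487 genes for the hepatocyte condition against undifferentiated cells, 3277 of them also passing here, and 153 for the cholangiocyte condition, 116 of them also passing here. Against the primary cells the authors' deposited table called 19714 and 2149 genes. Among genes called both here and in the authors' deposited table, the sign differed for 10 genes between the hepatocyte condition and primary hepatocytes, 15 between primary hepatocytes and undifferentiated cells, 3 between the primary cell types and 0 in the other comparisons. The fold in the authors' deposited table overflowed for 26, 33 and 10 genes in these comparisons, 6 between the conditions and 0 in the others, which were left out of the correlation.

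The test was tested on simulated data: noise of the measured size was drawn for 25975 genes around a mean common to all groups, and 100 genes each were given a log2 difference of 1 or 3. For a difference of 3 it recovered 81% of the genes in the hepatocyte condition against undifferentiated cells, 75% in the cholangiocyte condition, 84% and 72% against the primary cells, 70% between the conditions, 70% between the primary types, and 79% and 76% for the primary types against undifferentiated cells. For a difference of 1 it recovered 15%, 7%, 22%, 9%, 18%, 16%, 35% and 16% in the same order. False calls numbered 3 to 9 per comparison.

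Movement towards primary cells was computed with the undifferentiated arrays split into pairs, so that no array entered both differences, and averaged over the splits. The share of the distance covered is the regression slope of the change on the distance, with the variance of the distance taken from separate arrays. The values with shared arrays, and those of 20 simulated sets of unchanged groups, were computed beside them.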

Results

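Gene expression was measured with 17 single-colour Agilent mouse oligonucleotide arrays on adult liver progenitor cells, on the cells they gave in culture, and on mature liver cells. The mice carried Cre recombinase under the control of Foxl1, a forkhead transcription factor gene, and a yellow fluorescent protein reporter that Cre switches on for good, so that a cell that has used Foxl1 and its descendants are marked. The 5 groups were undifferentiated progenitor cells (n = 4), progenitors differentiated in culture into hepatocytes (n = 4, the hepatocyte condition) or into cholangiocytes, the cells that line bile ducts (n = 3, the cholangiocyte condition), primary hepatocytes (n = 4) and primary cholangiocytes (n = 2). The stated design compared the cells differentiated in culture with the primary cells. The 75th percentile of intensity per array was 2375 ± 191 (SD) in undifferentiated cells, 2021 ± 132 and 1856 ± 139 in the hepatocyte and cholangiocyte conditions, 801 ± 189 in primary hepatocytes and 2767 ± 115 in primary cholangiocytes. Between 23894 and 29225 probes per array were well above background. The small number of arrays limits the precision, and the labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples.

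Values are log2 intensities relative to the 75th percentile of the array, given as mean ± SD. Differences are log2, first group minus second, ± the standard error (SE) of a limma fit to all 17 arrays. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over 25975 genes. Lists of genes fixed in advance were tested with camera at its preset correlation, and the adjusted p with a correlation estimated from the data stands beside it. A gene that was not well above background on any array of 1 of the groups has only a lower bound. It is written as at least N-fold, computed from the background level of that group. Normexp background correction, which compresses values near background, made 46 of the 189 named differences that passed over 1.5 times smaller and ended none of these calls. The arrays lay on 5 slides, and values with slide as a block or within single slides stand beside many of the results.

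Arrays of the same group correlated across genes with a mean r of 0.965 in the hepatocyte condition, 0.970 in undifferentiated cells and in the cholangiocyte condition, 0.979 in primary hepatocytes and 0.947 in primary cholangiocytes. Between groups, undifferentiated cells and the cholangiocyte condition were the most alike (mean r = 0.965), and primary hepatocytes and primary cholangiocytes the least (0.766). With primary hepatocytes the hepatocyte condition correlated at 0.811, while undifferentiated cells correlated with these primary cells at 0.779. With primary cholangiocytes the cholangiocyte condition correlated at 0.913, while undifferentiated cells correlated with these primary cells at 0.915. The main principal component (PC1) held 60.1% of the variance and separated primary hepatocytes from the other arrays, PC2 (10.2%) separated primary cholangiocytes, and PC3 (7.1%) separated the hepatocyte condition.

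**Figure D1:**
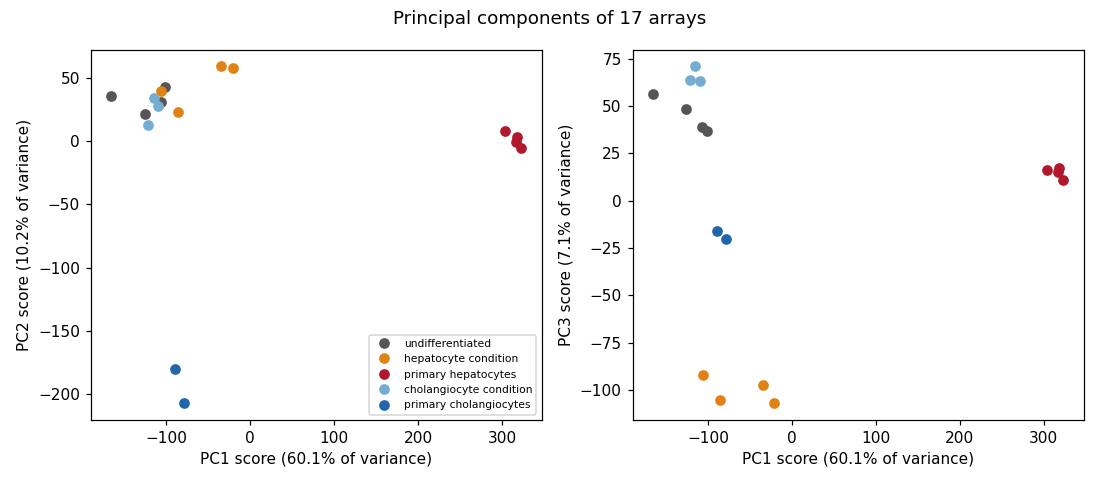
Principal component scores of the 17 arrays (points, coloured by group), with PC1 on the horizontal axes and PC2 or PC3 on the vertical axes. Primary hepatocytes lie apart on PC1 (60.1% of the variance), and the hepatocyte condition lies at the negative end of PC3 (7.1%).

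The first comparison asked which genes change when the progenitors are put under hepatocyte differentiation. In the hepatocyte condition, 18 of 42 plasma protein genes and 22 of 29 interferon-stimulated genes rose, and 36 of 48 cell cycle and 18 of 24 cholesterol synthesis genes fell. Of all lists only that of interferon-stimulated genes passed with an estimated correlation. Lrg1, which encodes a secreted acute-phase glycoprotein, rose by 10.13 ± 0.75 (adjusted p = 2.18e-06, n = 4 and 4), from -4.30 ± 1.55 to 5.83 ± 0.60. Serpina10, a plasma protease inhibitor, rose by 8.68 ± 0.30 (adjusted p = 9.88e-10). G6pc, the last enzyme of glucose release, rose by 5.46 ± 1.07 (adjusted p = 0.00379), whereas Alb, the gene of serum albumin, differed by 3.18 ± 3.24 (adjusted p = 0.601). In all, 1979 genes rose and 2000 fell, of which 1395 and 934 changed at least 2-fold.

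Other large increases among genes above background on every array were those of Itih4, a plasma matrix-stabilising protein (8.95 ± 1.21, adjusted p = 0.000307), the fibrinogen chain Fgb (8.22 ± 1.37) and the complement component C4b (8.20 ± 0.75). Of 42 plasma protein genes, 18 rose, none fell and 24 did not pass (21 rose when adjusted over the list alone). Fgg, another fibrinogen chain, rose by 11.21 ± 1.60 and the lipoprotein cofactor Apoh by 7.82 ± 1.38, while plasminogen (Plg), not above background in undifferentiated cells, did not pass (adjusted p = 0.0559). The list had a median of 3.53 (adjusted p = 4.72e-13, and 0.341 with an estimated correlation). With slide as a block its median was 3.15, but within single slides it was 0.73, -0.30 and 6.48. Each slide held a single array per group, and none of these pairs varied alike (r = -0.071, -0.15 and -0.064). On the slide with -0.30, Alb was 6.00 in undifferentiated cells and -3.65 in the condition. On that with 6.48 it was -4.44 and 7.62. The within-slide values of all lists in this comparison rest on these pairs. Of 21 complement genes 9 rose and 12 did not pass (15 rose when adjusted over the list alone), among them Cfhr2 (5.17 ± 0.45) and the central component C3 (4.39 ± 0.69). The complement median was 2.63, or 2.14 with genes below background at their bound (adjusted p = 7.77e-09, and 0.229 with an estimated correlation), and within slides 0.92, -0.22 and 4.45.

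Enzymes of mature hepatocytes rose in part. Of 40 cytochrome P450 and conjugation enzymes, 10 rose and 30 did not pass (13 rose when adjusted over the list alone). Cyp4f14, a fatty acid hydroxylase, rose by 5.96 ± 0.66. Cyp3a11, the main drug-oxidising P450 of mouse liver, differed by 3.32 ± 1.38 (adjusted p = 0.129). The P450 median was 2.06, or 1.94 at the bounds (adjusted p = 2.96e-08, and 0.344 with an estimated correlation). Of 36 urea cycle and amino acid genes 4 rose (8 when adjusted over the list alone). Of 19 glucose and glycogen genes 6 rose (7 when adjusted over the list alone), and of 23 bile acid genes 2 rose (9 when adjusted over the list alone). The medians of these lists were 2.33, 2.45 and 1.14, with adjusted p of 0.42, 0.402 and 0.344 with an estimated correlation. Within slides the P450 median was 0.58, -0.44 and 3.60, and the urea cycle median -0.26, -0.50 and 4.77. Of 25 liver transcription factors 9 rose and 16 did not pass (11 rose when adjusted over the list alone). Onecut1, a factor of hepatoblasts, rose by 5.02 ± 0.79 (adjusted p = 0.000951), while Hnf4a (-0.11 ± 0.45), the nuclear receptor of hepatocyte identity, and Cebpa (0.38 ± 0.50), a factor of mature hepatocytes, did not pass.

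Single arrays of this condition differed. Alb was 7.62, -4.76, 7.58 and -3.65 on the 4 arrays of the hepatocyte condition and 6.00, 1.26, -4.44 and -8.74 on those of undifferentiated cells, the last not above background. The mean of the plasma protein list was 3.40, -0.17, 4.07 and -0.76 in the hepatocyte condition. Leaving out array 2 or array 4 of the condition brought Cyp3a11 past the threshold (adjusted p = 0.0482 and 0.0352; 0.0352 to 0.316 over its alternatives), and Plg likewise (0.0271 and 0.00864; 0.00864 to 0.196 over its alternatives). Cyp3a11 also passed as the mean of its probes, at 5.23 (adjusted p = 0.0499), and Plg with the filter that asks for every array of a group (0.0478).

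Of 29 interferon-stimulated genes 22 rose and 7 did not pass, with the same counts when adjusted over the list alone. The list had a median of 3.04 (adjusted p = 1.35e-21, and 0.0208 with an estimated correlation), 3.03 with slide as a block, and 2.10, 3.22 and 2.97 within slides. Oas2, an activator of RNA decay, rose by 7.29 ± 0.76 (adjusted p = 4.62e-05), Ifi44 by 5.76 ± 0.55, the antiviral enzyme Rsad2 by 5.47 ± 0.75 and Ifit1, which binds foreign RNA, by 4.99 ± 0.52. Leukocyte markers went with them in small number: of 36, 4 rose and 1 fell (adjusted over the list alone, also 4 and 1), with a list median of 0.13, or -0.13 with median scaling. H2-Ab1, an antigen-presenting class II chain, rose by 5.24 ± 0.86 and Ptprc, the CD45 gene, by 2.63 ± 0.53.

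Of 48 cell cycle genes 36 fell and none rose (43 fell when adjusted over the list alone). The list median was -1.75 (adjusted p = 7.96e-23, and 0.229 with an estimated correlation), -1.50 with slide as a block, and -1.94, -2.24 and -0.94 within slides. The spindle checkpoint kinase Bub1 (-2.92 ± 0.36), the ubiquitin enzyme Ube2c (-2.72 ± 0.39) and the mitotic cyclin Ccnb2 (-2.56 ± 0.46) fell. Of 24 cholesterol synthesis genes 18 fell and 1 rose (20 and 1 when adjusted over the list alone). Their median was -1.65 (adjusted p = 1.41e-11, and 0.341 with an estimated correlation), and -2.04, -2.90 and -1.98 within slides. Idi1 (-3.18 ± 0.58), Cyp51 (-2.87 ± 0.62) and Fdps (-2.38 ± 0.49), enzymes of the sterol pathway, fell, and Acat2, a thiolase, rose by 2.98 ± 0.62. The list of immediate-early and heat shock genes was also higher by camera at the preset correlation, with a median of 0.74 with slide as a block. It no longer passed by camera in some alternatives (adjusted p up to 0.171).

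Of 45 biliary markers 3 rose, 6 fell and 36 did not pass (4 and 7 when adjusted over the list alone), with a median of -0.16 (adjusted p = 0.537). The keratin Krt19 fell by 1.98 ± 0.50 (adjusted p = 0.016), but without array 3 of the condition it was -1.75 (adjusted p = 0.0517; range over its alternatives 0.00114 to 0.0517). The matrix metalloproteinase Mmp7 (5.19 ± 0.78) and the bile acid importer Slc10a2 (2.95 ± 0.51) rose, and the integrin Itgb6 fell by 4.23 ± 0.75. Krt7 (-0.78 ± 0.33) and Sox9 (0.78 ± 0.55), a biliary transcription factor, did not pass. Of 28 progenitor and fetal liver genes 2 rose and 4 fell (3 and 5 when adjusted over the list alone). The fetal growth factor Igf2 rose by 3.94 ± 0.68, the glypican Gpc3 was at least 28-fold higher (adjusted p = 6.47e-05), and the tetraspanin Cd9 fell by 0.82 ± 0.21. Foxl1 itself was 1.07 ± 1.86 in undifferentiated cells, 0.46 ± 1.68 in the hepatocyte condition and -0.35 ± 3.47 in the cholangiocyte condition, and was not above background in either primary cell type. The Notch ligand Dll1 rose by 4.12 ± 0.39, while the feedback gene Nrarp (-3.25 ± 0.28) and the ligand Jag1 (-1.95 ± 0.32) fell. Among genes above background on every array of both groups, the largest decreases besides Itgb6 were of the bicarbonate transporter relative Slc4a11 (-6.01 ± 0.56, adjusted p = 1.67e-05), Rasgrp3, a Ras activator (-5.14 ± 0.80), Sprr1a, a cornified envelope protein (-4.92 ± 0.85), Misp3 (-4.50 ± 0.74) and Gsta1 (-4.05 ± 0.96), whose probe cannot be told with certainty from its paralogs.

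The median over all genes was 0.07, and -0.18 with scaling to the median of each array, where 1115 genes rose and 2771 fell. When slide was a block 3102 genes passed, 2872 of them shared, and of the genes that passed without a given slide 96.3%, 90.8% and 95% had the same sign within it.

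**Figure D2:**
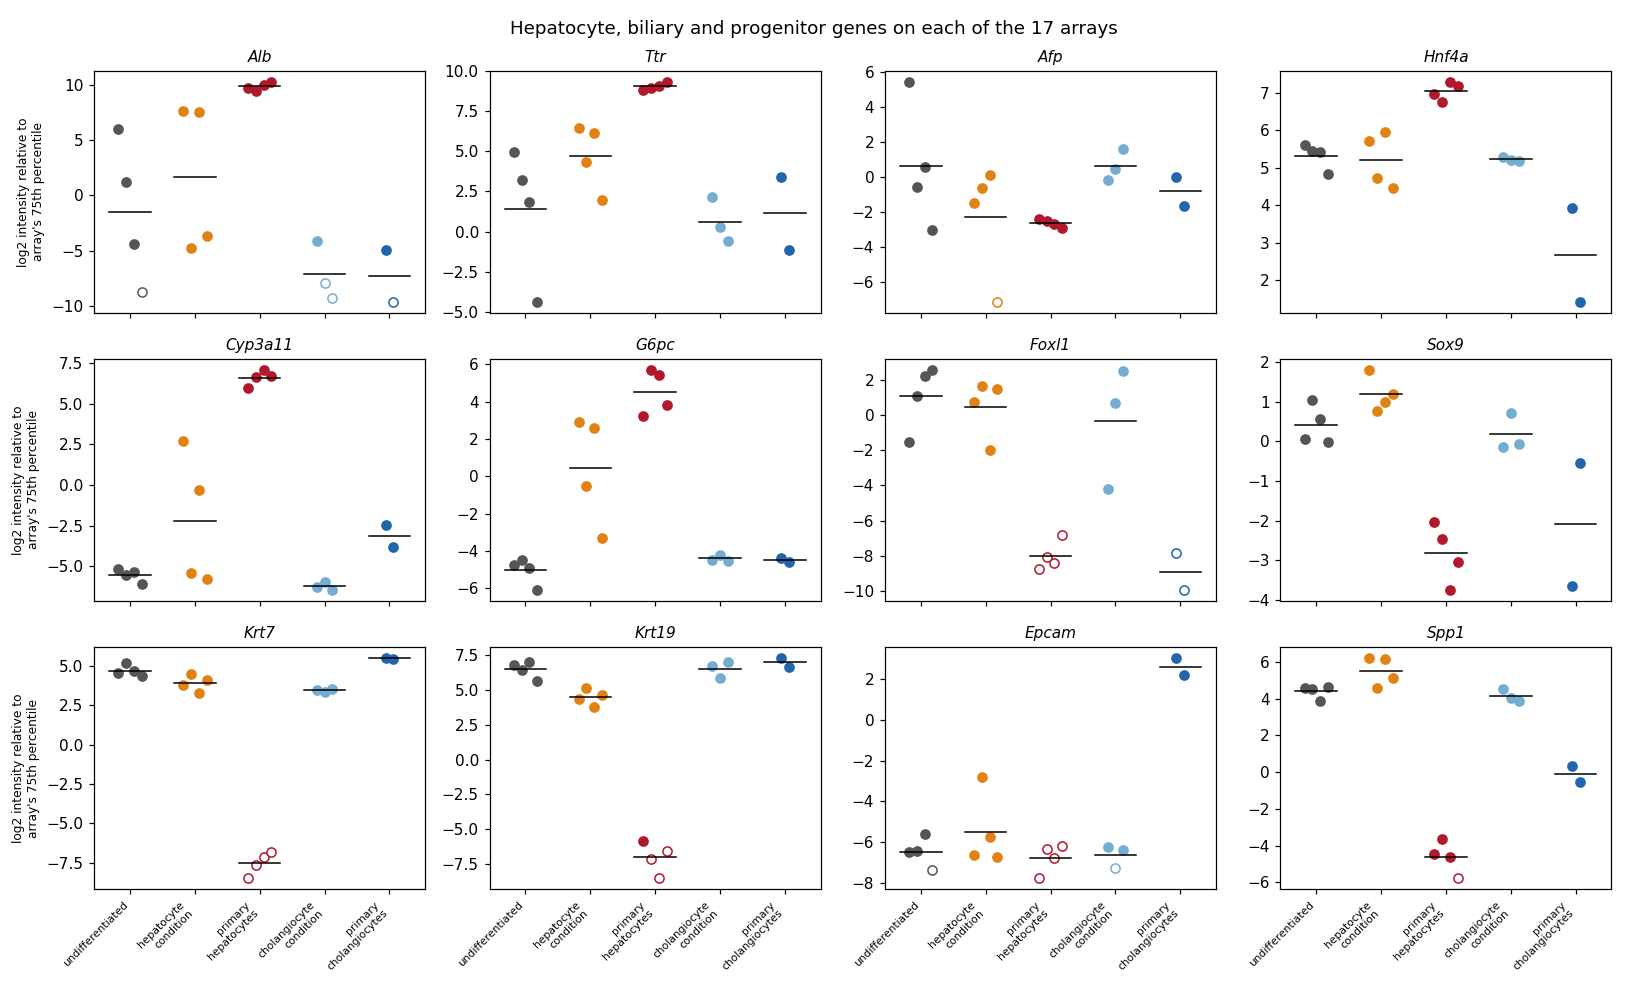
Log2 intensity relative to the 75th percentile of the array (vertical axes) of 12 hepatocyte, biliary and progenitor genes on each of the 17 arrays, by group (horizontal axes). Open points were not well above background and bars are group means; Alb ranges from -4.76 to 7.62 in the hepatocyte condition, and Epcam is above 2 in primary cholangiocytes alone.

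The second comparison asked the same of cholangiocyte differentiation. Few genes passed: 204 rose and 155 fell (n = 3 and 4), of which 181 and 139 changed at least 2-fold. In simulated data 7% of genes with a log2 difference of 1 were recovered in this comparison, so changes of that size could be missed. Fosb, an immediate-early subunit of the AP-1 transcription factor, rose by 6.83 ± 0.76 (adjusted p = 0.000553), from -4.87 ± 0.32 to 1.95 ± 0.52. Biliary keratins showed no change that passed: Krt19 differed by 0.05 ± 0.54 (adjusted p = 0.984) and Krt7 by -1.23 ± 0.36 (adjusted p = 0.124), although Krt7 passed with normexp background correction (0.0365; range over its alternatives 0.0365 to 0.339). Of the 45 biliary markers none passed, over all genes or adjusted over the list alone, and their median was 0.01 (adjusted p = 0.462), -0.13 with slide as a block.

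Tgfbi, a matrix protein induced by TGF-beta, rose by 5.27 ± 0.75 (adjusted p = 0.00341) and the Wnt co-receptor Lgr5 by 4.84 ± 0.67 (adjusted p = 0.00305), the only progenitor gene of 28 to pass. Slc17a1, a phosphate and urate transporter, fell by 3.96 ± 0.44. Of 26 immediate-early and heat shock genes 5 rose and none fell (5 and 0 when adjusted over the list alone). Their median was 0.84 (adjusted p = 6.68e-05, and 0.366 with an estimated correlation), 1.07 with slide as a block, and 0.87 and 0.56 within slides. Jun, an AP-1 subunit, rose by 3.12 ± 0.52 (adjusted p = 0.00912), but its adjusted p was 0.0526 without array 2 of the condition (range over its alternatives 0.000789 to 0.0526). Of 24 cholesterol synthesis genes 1 passed, against 17 when adjusted over the list alone. That list had a median of -1.25 (adjusted p = 4.77e-19, and 0.366 with an estimated correlation), -1.44 with slide as a block and -1.40 and -1.64 within slides. Among 29 interferon-stimulated genes the chemokine Cxcl10 rose by 2.99 ± 0.46 and 1 gene fell (1 and 2 when adjusted over the list alone), with a median of -0.47 (adjusted p = 0.00101, and 0.882 with an estimated correlation). In a fit to the compared groups alone Cxcl10 had an adjusted p of 0.0604 (range over its alternatives 0.00236 to 0.0604).

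Hepatocyte genes did not rise. Among 42 plasma protein genes 1 fell, Itih2 (-3.82 ± 0.57, adjusted p = 0.00439, but 0.123 in a fit to the compared groups alone; range over its alternatives 0.00151 to 0.123), and none rose (3 and 0 when adjusted over the list alone). The plasma protein median was -0.93 (adjusted p = 8.05e-05, and 0.896 with an estimated correlation), but -2.52 and 0.08 within slides. None of 36 urea cycle, 19 glucose, 21 complement or 26 fatty acid oxidation genes passed. Alb (-5.64 ± 3.50), Hnf4a (-0.10 ± 0.48), Sox9 (-0.24 ± 0.60), Spp1 (-0.26 ± 0.48), Epcam (-0.15 ± 0.78) and Foxl1 (-1.42 ± 1.41) did not pass either. None of 48 cell cycle, 36 leukocyte or 9 red blood cell genes passed over all genes. As lists, cell cycle, YAP target and fatty acid oxidation genes passed by camera at the preset correlation, but not with an estimated one. Each no longer passed in some alternatives. By camera, cell cycle had an adjusted p of 0.173 with normexp background correction (median 0.30). YAP targets had 0.271 with a block by replicate number (median -0.08).

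Over all genes the median was 0.14, and -0.05 with median scaling, where 113 genes rose and 190 fell; with quantile normalization 132 rose and 173 fell. Leaving out 1 array gave 128 genes without array 2 of the condition, 228 without array 1, 181 without array 3, and 199 and 176 without undifferentiated arrays 2 and 3. With slide as a block 181 passed, 155 of them shared, and within slides 90.3% and 92.3% of genes that passed without that slide had the same sign.

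The next comparison asked how far the conditions part from each other. In the hepatocyte condition 18 of 42 plasma protein, 7 of 21 complement and 21 of 29 interferon-stimulated genes were higher, and 42 of 48 cell cycle genes were lower. Only the interferon-stimulated genes passed as a list with an estimated correlation. The fibrinogen chain Fgb was higher by 11.34 ± 1.48 (adjusted p = 0.000234, n = 4 and 3) and Lrg1 by 10.00 ± 0.81, while the chemokine Ccl7 was lower, at -6.78 ± 0.53 (adjusted p = 4.56e-06). In all, 1811 genes were higher and 2184 lower in the hepatocyte condition, 1374 and 1186 of them at least 2-fold.

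Kng1, the precursor of bradykinin (10.54 ± 1.49), Itih4 (10.36 ± 1.30), the protease inhibitor Serpina3m (10.34 ± 1.05) and C4b (8.90 ± 0.81) were also among the largest increases, and Fgg was at least 29500-fold higher (adjusted p = 6.51e-05). Of 42 plasma protein genes 18 were higher and none lower (27 and 0 when adjusted over the list alone). Their median was 5.09, or 4.48 at the bounds (adjusted p = 2.11e-18, and 0.217 with an estimated correlation), and 4.01, 6.86 and 5.62 within slides. Of 40 P450 and conjugation enzymes 13 were higher, over all genes and when adjusted over the list alone, among them the drug-oxidising Cyp2d10 (9.32 ± 1.49) and the sulfotransferase Sult1a1 (7.69 ± 0.85). The P450 median was 1.80, or 1.57 at the bounds, with an adjusted p of 0.374 with an estimated correlation. Of 21 complement genes 7 were higher (10 when adjusted over the list alone), with C4bp, a regulator of the classical pathway, at 5.82 ± 0.69. Of 25 liver transcription factors 6 were higher, while Hnf4a was at -0.01 ± 0.48 (adjusted p = 0.997). Ppara, the receptor of fatty acid catabolism, was higher by 3.79 ± 0.60. Alb differed by 8.82 ± 3.50 (adjusted p = 0.112, but 0.0427 with a block by replicate number; range over its alternatives 0.0427 to 0.267).

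Among 29 interferon-stimulated genes 21 were higher and none lower (23 and 0 when adjusted over the list alone), with a median of 3.38 (adjusted p = 4.03e-27, and 0.00783 with an estimated correlation), and 2.61, 3.42 and 3.89 within slides. Oas2 was at 7.69 ± 0.83, Ifi44 at 7.10 ± 0.59 and Rsad2 at 6.96 ± 0.81. Of 48 cell cycle genes 42 were lower (47 when adjusted over the list alone), with a median of -2.09, or -2.06 at the bounds (adjusted p = 1.94e-24, and 0.204 with an estimated correlation), and -2.33, -1.50 and -1.60 within slides. Kif23, a motor of cell division, was at -3.30 ± 0.54 and Bub1 at -3.23 ± 0.39. Among 45 biliary markers 3 were higher and 5 lower, over all genes and when adjusted over the list alone. Their median was -0.20 while camera leaned upward (adjusted p = 0.891). Mmp7 was higher by 5.99 ± 0.85, Itgb6 at -5.57 ± 0.81, and Krt7 (0.46 ± 0.36) and Epcam (1.15 ± 0.78) did not pass. Lgr5 (-4.04 ± 0.67), the Notch target Hey1 (-4.45 ± 0.75), Fosb (-6.18 ± 0.76), Sprr1a (-6.32 ± 0.92) and Ptgs2, the inducible prostaglandin synthase (-6.01 ± 0.59), were lower in the hepatocyte condition.

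The median over all genes was -0.13. The count was 2641 without array 1 and 2651 without array 2 of the cholangiocyte condition. When slide was a block 3496 genes passed, 3194 of them shared, and 97.9%, 95.6% and 94.4% of genes that passed without a slide had the same sign within it.

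The hepatocyte condition was then set against primary hepatocytes, the comparison named in the design. In the cultured cells 38 of 40 P450 and conjugation enzymes and 33 of 42 plasma protein genes were lower. There 29 of 45 biliary, 15 of 28 progenitor, 35 of 48 cell cycle and 19 of 23 YAP target genes were higher, against 5, 5, 3 and 0 that were lower. No list passed with an estimated correlation. Cyp1a2, a drug-oxidising P450, was lower, at -12.51 ± 0.95 (adjusted p = 6.49e-08, n = 4 and 4), and Cyp7a1, the first enzyme of bile acid synthesis, was at least 997-fold lower (adjusted p = 8.52e-09). Krt19 was higher by 11.51 ± 0.50 (adjusted p = 2.24e-10), and S100a6, a calcium-binding protein of proliferating cells, by 11.83 ± 0.18, at 7.53 ± 0.12 against -4.30 ± 0.37. Krt19 was well above background on only 1 of 4 primary hepatocyte arrays, so the size of its difference is uncertain (7.86 to 12.36 over its alternatives). In all, 6745 genes were higher and 8753 lower in the hepatocyte condition.

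Among genes above background on every array of both groups, the largest decreases were of the major urinary proteins, secreted pheromone carriers, from Mup9 (-15.63 ± 0.62, adjusted p = 7.56e-11) to Mup20 (-14.52 ± 0.82). Their members are near-identical, so that which of them was measured is uncertain. Among 42 plasma protein genes 33 were lower and none higher (34 when adjusted over the list alone), with a median of -4.84 (adjusted p = 1.28e-06, and 0.28 with an estimated correlation), and -6.29, -7.34 and -2.53 within slides. The corticosteroid carrier Serpina6 was at -11.40 ± 0.86 and antithrombin (Serpinc1) at -10.22 ± 1.83. Alb was at -8.19 ± 3.24 (adjusted p = 0.0416) and Ttr, the thyroid hormone carrier, at -4.34 ± 1.67 (adjusted p = 0.0369). Neither call held over the alternatives. Quantile normalization ended both, with Alb at -6.89 (adjusted p = 0.0739; range over its alternatives 0.00983 to 0.131) and Ttr at -3.24 (0.102; range over its alternatives 0.00409 to 0.114). Without arrays 2 and 4 of the hepatocyte condition Alb was at -6.04 and -6.41 (0.131 and 0.126), and Ttr at -4.20 and -3.42 (0.0711 and 0.114). Leaving out any 1 of the primary hepatocyte arrays also ended both calls, with differences of -8.34 to -8.05 for Alb (0.0679 to 0.0757) and -4.41 to -4.24 for Ttr (0.0609 to 0.0699).

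Of 40 P450 and conjugation enzymes 38 were lower, with a median of -8.89, or -8.75 at the bounds (adjusted p = 3.11e-12, and 0.123 with an estimated correlation), and -9.66, -10.86 and -6.39 within slides. Cyp3a11 was at -8.79 ± 1.38 and Ugt2b1, a glucuronidating enzyme, at -12.43 ± 0.39. Of 36 urea cycle and amino acid genes 34 were lower (median -8.85, 0.162 with an estimated correlation), with Agxt, which clears glyoxylate, at -11.89 ± 0.78 and Tat, a tyrosine transaminase, at -9.17 ± 0.51. Of 19 glucose and glycogen genes 18 were lower (median -4.13, 0.162 with an estimated correlation), with liver glycogen synthase Gys2 at -11.05 ± 1.21 and G6pc at -4.11 ± 1.07. Of 23 bile acid genes 22 were lower and 1 higher (median -7.53, 0.0877 with an estimated correlation). Akr1c6, a steroid dehydrogenase, was at -15.25 ± 0.46 and the uptake carrier Slco1b2 at -13.04 ± 1.13, against the oxysterol hydroxylase Cyp39a1 at 2.13 ± 0.40. All 26 fatty acid oxidation genes were lower (median -2.96, 0.107 with an estimated correlation), with the fatty acid ligase Slc27a2 at -10.92 ± 1.83. Of 21 complement genes 18 were lower (median -3.71, 0.132 with an estimated correlation); C8a, a chain of the membrane attack complex, was at least 8080-fold lower, and C3 was at -1.22 ± 0.69 (adjusted p = 0.141, but 0.000438 in a fit to the compared groups alone; range over its alternatives 0.000438 to 0.873). Of 25 liver transcription factors 19 were lower and 2 higher (median -2.22, 0.123 with an estimated correlation), with the circadian factor Hlf at -8.45 ± 0.32, Cebpa at -5.45 ± 0.50 and Hnf4a at -1.83 ± 0.45, against the pioneer factor Foxa2 at 1.20 ± 0.20. These 6 lists gave the same counts when adjusted over the list alone. Of 24 cholesterol synthesis genes 23 were lower (median -3.41, 0.196 with an estimated correlation), with Insig1, the brake on sterol sensing, at -6.29 ± 0.59.

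Of 45 biliary markers 29 were higher, 5 lower and 11 did not pass, also when adjusted over the list alone. Their median was 2.30, or 1.92 at the bounds (adjusted p = 1.16e-08, and 0.0877 with an estimated correlation), and 2.80, 1.94 and 2.48 within slides. Krt7 was at least 1030-fold higher (adjusted p = 3.17e-12) and the cell surface protein Cd24a at least 1900-fold. The secreted phosphoprotein Spp1 was at 10.14 ± 0.44 and Sox9 at 4.01 ± 0.55, while Epcam did not pass (adjusted p = 0.137, but 0.0414 with quantile normalization; 0.0414 to 0.491 over its alternatives) and the water channel Aqp1 was at -4.22. Of 28 progenitor genes 15 were higher and 5 lower (16 and 6 when adjusted over the list alone), with a median of 4.04, or 3.21 at the bounds (0.0877 with an estimated correlation). The neural adhesion molecule Ncam1 was at 9.86 ± 0.47 (5.62 as the mean of its probes), Lgr5 at -4.59 ± 0.62, and Foxl1 at least 94.5-fold higher (adjusted p = 6.98e-05). Of 48 cell cycle genes 35 were higher and 3 lower, also when adjusted over the list alone (median 2.80, 0.162 with an estimated correlation), with the DNA topoisomerase Top2a at 5.61 ± 0.44, the mitotic kinase Plk1 at 5.19 ± 0.54 and the replication factor Mcm10 at -6.27 ± 0.36. Of 23 YAP targets 19 were higher and none lower, also when adjusted over the list alone (median 2.50, adjusted p = 5.95e-09, and 0.0877 with an estimated correlation), with the muscle ankyrin protein Ankrd1 at 11.66 ± 0.62 and Ccn2, a matrix growth factor, at 10.41 ± 0.49. Of 41 extracellular matrix genes 21 were higher and 5 lower (median 1.78, 0.0959 with an estimated correlation), with the intermediate filament Vim at 9.28 ± 0.76 and the protease inhibitor Timp1 at least 2950-fold higher. Of 21 Notch pathway genes 12 were higher and 6 lower, and Jag1 was at 3.27 ± 0.32 and Hes1, a Notch target, at 3.28 ± 0.44.

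Markers of other liver cells were also higher in the primary hepatocytes. Of 25 endothelial markers 21 were lower in the hepatocyte condition and 1 higher (median -4.01, or -2.42 at the bounds; adjusted p = 4.05e-06, and 0.0959 with an estimated correlation), with the scavenger receptor Stab2 at -6.60 ± 0.80 and the guidance receptor Robo4 at -7.58 ± 0.55. Of 36 leukocyte and Kupffer cell markers 28 were lower and 3 higher (30 and 3 when adjusted over the list alone; median -2.01, or -1.98 at the bounds, 0.162 with an estimated correlation). The Kupffer cell lectin Clec4f was at least 33.1-fold lower, against the lipopolysaccharide receptor Cd14 at 7.55 ± 0.30. Of 9 red blood cell genes 7 were lower and 1 higher (median -4.16, or -4.07 at the bounds, 0.162 with an estimated correlation), and Alas2, the heme enzyme of red cells, was at least 2780-fold lower. Of 15 stellate cell markers 2 were higher and 8 lower (2 and 9 when adjusted over the list alone; median -1.37, adjusted p = 0.107), with the retinol-storing enzyme Lrat at -4.42 ± 0.66. Of 29 interferon-stimulated genes 12 were higher and 8 lower, with a median of 0.36, 0.2 with slide as a block, and -0.02, 0.79 and 0.56 within slides. The list did not pass by camera at the preset correlation. It did in some alternatives, such as normexp background correction (median 0.09, adjusted p = 0.00421 by camera). Oas2 was at 6.16 ± 0.76 and Psmb9, an immunoproteasome subunit, at -1.64.

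Over all genes the median was -0.33, -0.15 with median scaling and -0.01 with quantile normalization, and normexp background correction gave 5471 genes higher and 14235 lower. With slide as a block 16612 genes passed, 14781 of them shared, and 98.2%, 97.9% and 97.6% of genes that passed without a slide had the same sign within it.

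**Figure D3:**
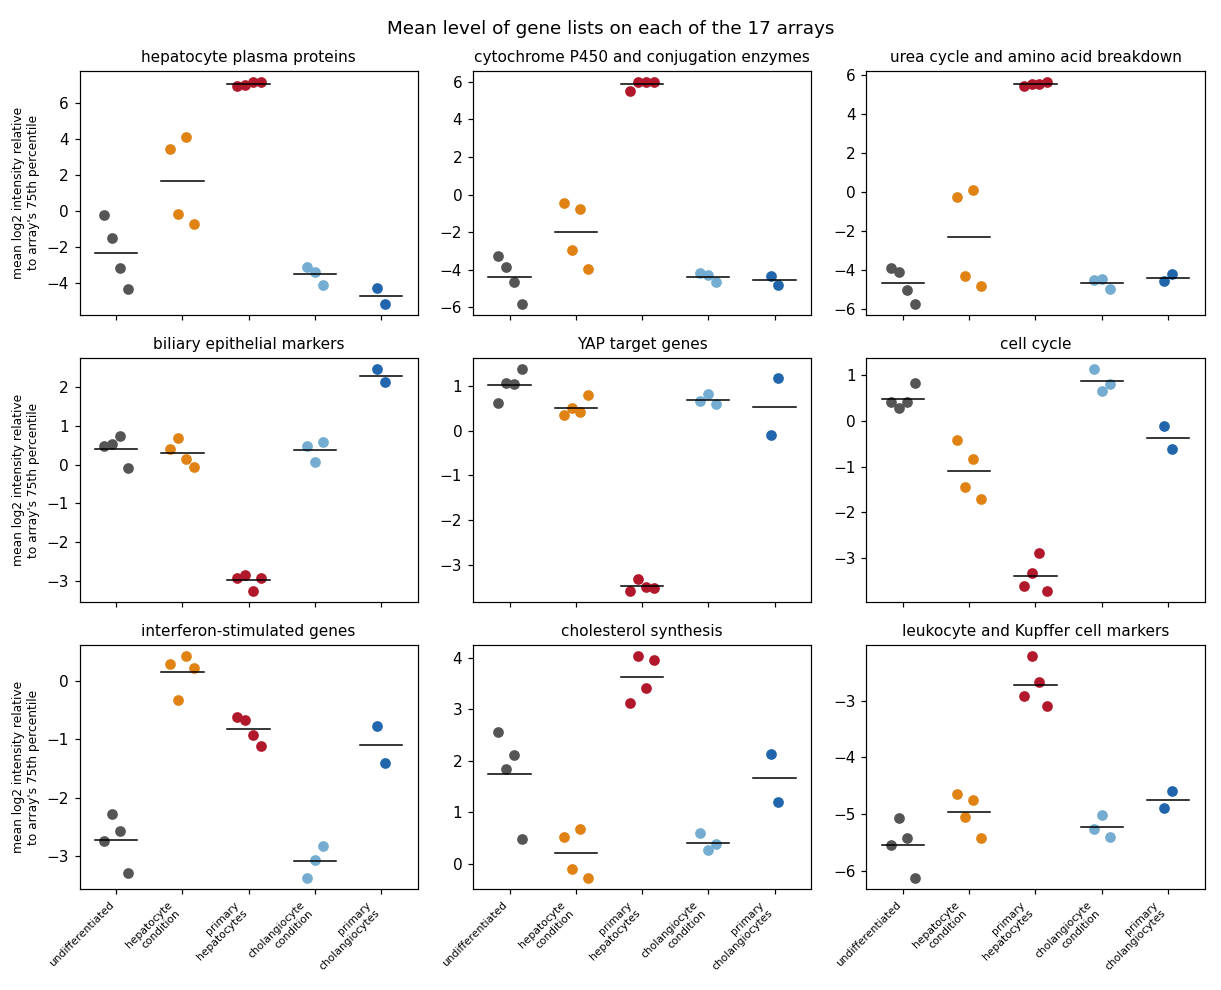
Mean log2 intensity relative to the 75th percentile of the array (vertical axes) of 9 gene lists on each of the 17 arrays, by group (horizontal axes), with bars at group means. The plasma protein mean is 7.05 in primary hepatocytes, 1.64 in the hepatocyte condition and -2.33 in undifferentiated cells.

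The cholangiocyte condition was set against primary cholangiocytes. In the cultured cells 14 of 45 biliary markers were lower and 9 higher, and 8 of 42 plasma protein and 13 of 48 cell cycle genes were higher. As lists, none passed with an estimated correlation. Epcam, an epithelial adhesion molecule, was at -9.26 ± 0.93 (adjusted p = 1.47e-05, n = 3 and 2) and Mmp7 at -11.85 ± 1.01, from 7.24 ± 0.72 in primary cells to -4.61 ± 0.65. The retinol carrier Rbp4 was at 12.08 ± 0.40 (adjusted p = 6.88e-10), and Krt19 did not pass (-0.46 ± 0.65, adjusted p = 0.71). In all, 3103 genes were higher and 1984 lower, 2010 and 1689 of them at least 2-fold.

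Among 45 biliary markers 9 were higher, 14 lower and 22 did not pass (9 and 17 when adjusted over the list alone). Their median was -0.56 (adjusted p = 0.000486, and 0.426 with an estimated correlation), -0.62 with slide as a block and -1.11 within the 1 slide that held both groups. The water channel Aqp5 (-10.62 ± 0.85), the mucin Muc1 (-9.83 ± 0.74), the tight junction protein Cldn7 (-9.32 ± 0.30) and Krt7 (-2.03 ± 0.43) were lower. Spp1 (4.26 ± 0.57) was higher. Chga, a neuroendocrine granule protein (-11.16 ± 0.60), the lipid desaturase Degs2 (-11.12 ± 1.22) and the collectin Sftpd (-10.58 ± 0.72) were among the largest decreases. The lectin Lgals2 (9.79 ± 1.27), Ccl7 (9.39 ± 0.63) and the lipoprotein Apob (9.18 ± 0.43) were among the largest increases. Of 42 plasma protein genes 8 were higher and 1 lower, also when adjusted over the list alone (median 0.31, adjusted p = 0.251), with transferrin (Trf) at 6.92 ± 0.59. Of 25 liver transcription factors 6 were higher and 2 lower (7 and 2 when adjusted over the list alone). Hnf4a was at 2.55 ± 0.58 (adjusted p = 0.00708), but 1.29 without array 4 of primary cholangiocytes (adjusted p = 0.0967), and it did not pass in a fit to the compared groups alone (0.154; range over its alternatives 0.000332 to 0.154).

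Of 48 cell cycle genes 13 were higher and none lower (14 when adjusted over the list alone), with a median of 1.19 (adjusted p = 3.51e-07, and 0.982 with an estimated correlation), and 1.24 within the slide. The replication helicase Mcm6 was at 2.28 ± 0.32. Of 28 progenitor genes 9 were higher and 3 lower (10 and 5 when adjusted over the list alone). Their median was 0.89 (adjusted p = 0.773), and 0.5 with slide as a block. The RNA-binding protein Igf2bp1 was at 7.97 ± 0.64, Lgr5 at least 66.7-fold higher, and the stem cell factor receptor Kit at least 260-fold lower (adjusted p = 7.57e-06). Of 41 matrix genes 12 were higher and 3 lower, also when adjusted over the list alone. Their median was -0.08, their mean 0.80, and camera leaned upward (adjusted p = 0.323). The mesenchymal regulator Zeb1 was at 7.55 ± 0.32 and the matrix protein Sparc at 5.84 ± 0.51. Among 29 interferon-stimulated genes 18 were lower and 2 higher (20 and 2 when adjusted over the list alone), with a median of -1.58 (adjusted p = 8.95e-09, and 0.365 with an estimated correlation) and -1.21 within the slide. Rsad2 was at -6.91 ± 0.97 and Ifi44 at -6.29 ± 0.71. Of 24 cholesterol synthesis genes 7 were lower (9 when adjusted over the list alone; median -1.40, adjusted p = 1.1e-05, and 0.982 with an estimated correlation). The leukocyte marker Cd68 was at -4.29 ± 0.43, while the endothelial genes Ptprb (5.32 ± 0.50) and Vwf (-4.16 ± 0.84) went opposite ways.

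The median over all genes was 0.17, and normexp background correction gave 5409 genes higher and 1819 lower. When slide was a block 4000 genes passed, 3691 of them shared, and 90.3% of genes that passed without the slide of both groups had the same sign within it.

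The primary cell types served as the measure of the lineage difference. Primary hepatocytes had 7272 genes higher and 5618 lower than primary cholangiocytes (n = 4 and 2). Alb was higher by 17.18 ± 3.97 (adjusted p = 0.00246), Hnf4a by 4.38 ± 0.55 and Cebpa by 5.62 ± 0.62. Krt7 was at least 3050-fold lower (adjusted p = 1.5e-11), Epcam at least 426-fold lower (adjusted p = 8.27e-07) and Krt19 at -14.00 ± 0.62. Alb was well above background on 1 of 2 primary cholangiocyte arrays and Krt19 on 1 of 4 primary hepatocyte arrays. The sizes of these 2 differences thus rest partly on values not above background.

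Among 42 plasma protein genes 41 were higher in primary hepatocytes (median 12.64, 0.116 with an estimated correlation), as were 38 of 40 P450 enzymes (10.49, 0.0794 with an estimated correlation) and all 36 urea cycle genes (10.44, 0.134 with an estimated correlation). The fetuin Ahsg was at 15.14 ± 2.92, the bilirubin and drug carrier Slco1b2 at 15.62 ± 1.39 and Bhmt, a methionine cycle enzyme, at 17.07 ± 2.14. Of 45 biliary markers 34 were lower and 4 higher, also when adjusted over the list alone, with a median of -5.67 (adjusted p = 5.03e-14, and 0.0141 with an estimated correlation), and -5.84 and -5.63 within slides. S100a6 (-11.72 ± 0.22), Ccn2 (-11.14 ± 0.60), the annexin Anxa1 (-10.35 ± 0.45) and the galectin Lgals3 (-9.89 ± 0.33) were among the largest decreases of genes above background on every array of both groups. Of 48 cell cycle genes 40 were lower and 3 higher (42 and 3 when adjusted over the list alone; median -3.34, or -3.22 at the bounds, 0.116 with an estimated correlation), and of 23 YAP targets 20 were lower and 1 higher (median -3.75, or -3.57 at the bounds, 0.0525 with an estimated correlation). Of 25 endothelial markers 18 were higher and 2 lower, and of 36 leukocyte markers 20 were higher and 3 lower (21 and 3 when adjusted over the list alone), with Stab2 at 7.47 ± 0.98 and C1qc, a Kupffer cell complement chain, at least 29.7-fold higher. Over all genes the median was 0.35, 0.15 with median scaling and 0.00 with quantile normalization, and normexp gave 14345 genes higher and 4807 lower. With slide as a block 14125 genes passed, 12148 of them shared, and within slides 91.9% and 94% of genes that passed without that slide had the same sign.

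The starting distance of the progenitors from the primary cells was measured against both types. Against undifferentiated cells, primary hepatocytes had 9772 genes higher and 6903 lower (n = 4 and 4). The ethanol-oxidising P450 Cyp2e1 was higher by 14.77 ± 1.16 (adjusted p = 7.25e-08), the bile acid ligase Slc27a5 by 13.29 ± 1.64 and Alb by 11.37 ± 3.24 (adjusted p = 0.00706). Krt7 was at least 1760-fold lower (adjusted p = 1.49e-12), S100a6 at -12.09 ± 0.18, Ankrd1 at -12.32 ± 0.62 and the desaturase Scd2 at -9.82 ± 0.41. All 40 P450 enzymes were higher (median 10.81, 0.118 with an estimated correlation), as were 41 of 42 plasma proteins and 20 of 25 transcription factors. Of 48 cell cycle genes 43 were lower and 2 higher (median -4.03, or -3.81 at the bounds, 0.119 with an estimated correlation). Among 45 biliary markers 30 were lower and 7 higher (median -2.48, 0.0899 with an estimated correlation). All these counts were the same when adjusted over the list alone. Leukocyte (30 of 36), endothelial (19 of 25) and red blood cell (7 of 9) markers were higher, with Robo4 at least 94-fold, H2-Ab1 at 7.14 ± 0.86 and Alas2 at least 2970-fold higher. Of 29 interferon-stimulated genes 21 were higher and 3 lower (median 2.01, 0.169 with an estimated correlation). The median over all genes was 0.44 and 0.00 with median scaling, where 7018 genes were higher and 8568 lower; quantile normalization gave 7442 and 8388, and normexp 14792 and 5845. When slide was a block 17039 genes passed, 16058 of them shared, and 97.4%, 98% and 97.3% of genes that passed without a slide had the same sign within it.

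Primary cholangiocytes had 2210 genes higher and 2745 lower than undifferentiated cells (n = 2 and 4), or 1497 and 3071 with median scaling, which moved the median over all genes from 0.01 to -0.24. Array weights and a fit to the compared groups alone each gave a count over 1.5 times lower. Mmp7 was higher by 11.04 ± 0.96 (adjusted p = 3.42e-06), Sftpd by 10.64 ± 0.68, Cldn7 by 9.23 ± 0.29 and Epcam by 9.11 ± 0.88. Rbp4 (-11.34 ± 0.38), the vitamin D carrier Gc (-9.91 ± 0.73), Apob (-8.95 ± 0.41), Trf (-8.76 ± 0.56) and haptoglobin (Hp, -8.05 ± 1.39) were lower, as were Spp1 (-4.53 ± 0.54) and Foxl1, at least 404-fold (adjusted p = 0.000656). Krt7 (0.79 ± 0.40) and Krt19 (0.51 ± 0.62) did not pass. Of 45 biliary markers 13 were higher and 8 lower (14 and 8 when adjusted over the list alone), with a median of 0.72 (adjusted p = 0.00123, and 0.588 with an estimated correlation). Of 42 plasma protein genes 10 were lower and none higher, also when adjusted over the list alone (median -1.78, or -1.48 at the bounds, 0.927 with an estimated correlation). Among 29 interferon-stimulated genes 16 were higher and 1 lower (18 and 1 when adjusted over the list alone; median 1.59, 0.588 with an estimated correlation). The count was 3222 without array 3 of primary cholangiocytes. With slide as a block 3535 genes passed, 3300 of them shared, and within the slide of both groups 85.2% of genes that passed without it had the same sign.

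Whether the distance from culture to primary cells differed between the lineages was tested with the difference of these differences, hepatocyte lineage minus cholangiocyte lineage. It passed for 9805 genes, 4034 positive and 5771 negative. The same contrast is the difference between the conditions minus that between the primary cell types, so a large difference between the primary types alone can give it. Among 45 biliary markers 31 were positive and 4 negative (31 and 5 when adjusted over the list alone), with a median of 5.25 (adjusted p = 1.11e-14, and 0.00977 with an estimated correlation) and 5.45 with slide as a block. Mmp7 was at 18.32 ± 1.28 (adjusted p = 1.07e-07). Among 42 plasma protein genes 27 were negative and none positive (29 and 0 when adjusted over the list alone; median -7.42, 0.271 with an estimated correlation), with Rbp4 at -14.24 ± 0.51 and Apob at -11.90 ± 0.55. Of 29 interferon-stimulated genes 16 were positive and 3 negative, also when adjusted over the list alone (median 2.28, 0.132 with an estimated correlation), with Oas2 at 11.63 ± 1.25. Over all genes the median was -0.44, and -0.10 with quantile normalization, where 5453 genes were positive and 4952 negative; normexp gave 3399 and 13589. When slide was a block 10964 genes passed, 9051 of them shared.

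The next measures asked whether the conditions parted along the lineage difference of primary cells. Across the 25975 genes, which are not independent replicates, the difference between the conditions correlated with that between the primary cell types at r = 0.244 (rho = 0.142), and at 0.18 to 0.295 with 1 array left out. Of 2521 genes that passed in both, 1860 (73.8%) had the same direction. Genes higher in the hepatocyte lineage in both numbered 823, against 507 from independent counts, and genes lower in both 1037, against 472.4. Of the 12890 genes that passed between the primary cell types, 57.8% had the same sign between the conditions, with 52.6% for those higher in primary hepatocytes and 64.5% for those higher in primary cholangiocytes.

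Movement towards the primary cells was measured across genes as the correlation of the change under differentiation with the difference between primary and undifferentiated cells, using different undifferentiated arrays for each. It was r = 0.365 (0.291 to 0.431 over the splits of those arrays) for the hepatocyte condition towards primary hepatocytes, and the change covered 15.6% of the distance along that direction (12.7% to 18.7% with 1 array left out). For the cholangiocyte condition towards primary cholangiocytes r was 0.073 (0.024 to 0.119) and the change covered 5.72% (3.31% to 8.50%). With normexp background correction this r fell below the range over the splits. Crossed between lineages, the hepatocyte condition gave r = 0.171 and 17.9% (15.3% to 19.6%) towards primary cholangiocytes, and the cholangiocyte condition r = 0.065 and 2.01% (-0.24% to 3.40%) towards primary hepatocytes. The share cannot be computed with 1 primary cholangiocyte array, so both percent ranges towards these cells omit leaving those arrays out. With any array left out, r towards them was 0.041 to 0.1 for the cholangiocyte condition and 0.143 to 0.183 for the hepatocyte condition. With the same undifferentiated arrays on both sides the r within lineages were 0.447 and 0.22, where simulated unchanged groups gave 0.501 and 0.377. In the simulation the primary cells were unchanged too, so its r come from shared noise alone and are no scale for the measured r. As covariances, the measured values were 1.271 and 0.246, where the simulated groups gave 0.135 and 0.135.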

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

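All tests of explanations in this part were chosen only after the results were seen, except the counts over other splits of the arrays.

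In groups of 4 arrays, a single array stood far from the rest for 3 of 107 measures tested, where chance alone would give about 5.3. Spp1 was 3.86 on undifferentiated array 3 against 4.53 to 4.64 on the others, a gap of 0.855 of the range of the group. The mean of red blood cell genes was -6.70 on undifferentiated array 4 against -5.71 to -5.55, a gap of 0.86 of the range. The mean of P450 and conjugation enzymes was 5.51 on primary hepatocyte array 1 against 5.96 to 5.99, a gap of 0.938 of the range.

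The difference between culture and primary cells differed between the lineages, by a test of the difference itself, for 9805 genes. It also did for the biliary markers as a list (median 5.25, adjusted p = 1.11e-14, and 0.00977 with an estimated correlation). The mean of the biliary list was 0.29 and 0.37 in the hepatocyte and cholangiocyte conditions, against -2.98 and 2.29 in primary hepatocytes and primary cholangiocytes. The list result thus mostly restates the difference between the primary cell types, which such markers are meant to show.

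The counts of genes that passed were compared with those of all 35 splits of the same arrays into groups of the same sizes. In the 5 comparisons with at least 3 arrays per group 1 split, the real one, gave as many. A share of 1 in 35 is the smallest that this test can give, and it was not adjusted over the 5 comparisons. Mixed splits put the group difference into the spread and so call few genes. The counts therefore do not exclude chance. For the hepatocyte condition against undifferentiated cells the real count was 3979 and the highest other 75, and for the cholangiocyte condition 359 and 74. The hepatocyte condition against primary hepatocytes gave 15498 and 5, the conditions against each other 3995 and 607, and primary hepatocytes against undifferentiated cells 16675 and 8.

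Hepatocyte genes differed between arrays of the same group, with Alb at 7.62, -4.76, 7.58 and -3.65 in the hepatocyte condition and from 6.00 to below background in undifferentiated cells. RNA carried over from mature hepatocytes would need 6.73% of the RNA on undifferentiated array 1 and 20.7% and 20.1% on arrays 1 and 3 of the hepatocyte condition to give the measured Alb. Of 99 other genes of mature hepatocytes, 82, 89 and 89 were below the level that those shares need, with medians of -5.81, -4.20 and -3.65. This argues against RNA with the profile of these primary hepatocytes as the whole source of Alb there. The needed levels were taken from primary hepatocytes, so the test cannot speak on hepatocytes whose profile had changed in culture. The shares also rest on the scaling of the arrays. An effect of the slide would move the groups on a slide together, but the slope of other groups on the plasma protein mean was -0.143 for the slides of the hepatocyte condition and -0.489 for those of undifferentiated cells. Across all genes, hepatocyte condition arrays 3 and 1 (Alb 7.58 and 7.62) varied most like undifferentiated arrays 1 and 2 (6.00 and 1.26). Arrays 2 and 4 (-4.76 and -3.65) varied most like undifferentiated arrays 3 and 4 (-4.44 and -8.74). High Alb in the condition thus went with higher Alb in the matched undifferentiated array. The match counts the hepatocyte genes themselves, and a source in the starting cells was not tested. Differences between cultures in the share of cells that differentiated, or in time in culture, stay open and were not tested.

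Interferon-stimulated genes were higher in the hepatocyte condition than in undifferentiated cells by a median of 3.04. Leukocyte RNA in these arrays would bring leukocyte markers with it, but their median was 0.13, and with slide as a block the interferon median was 3.03, so that neither explains the pattern as a whole. A response of the cells to the hepatocyte culture stays open as a hypothesis, because the medium, the time in culture and the cell state of each condition go with its group and cannot be separated in this design.

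Endothelial, leukocyte and red blood cell genes were higher in primary hepatocytes than in the hepatocyte condition, with medians of 4.01, 2.01 and 4.16. Scaling does not account for this, since before scaling the medians were 2.64, 0.64 and 2.78, the lowest 0.64, while that of all genes was -1.04. Of the markers, 23 of 25, 28 of 36 and 8 of 9 were above background on all primary hepatocyte arrays. RNA of other liver cells in the primary hepatocyte preparations stays open, because its test used the lists that showed the pattern (lowest median 2.01) and so could not decide. Expression of these genes by hepatocytes stays open too and was not tested. Of the endothelial markers 1 is also in another list, and the sort or gate used for primary hepatocytes is not given in the sources used here.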

How the results depend on the processing

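All alternatives here were chosen before the data were examined, and none was added later.

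Over alternatives other than leaving out arrays, 109 of 119 counts of genes that passed stayed within 1.5 times, and 10 did not. For the cholangiocyte condition against undifferentiated cells (359) the count was 181 with slide as a fixed block, 222 with a block by replicate number, 801 with array weights and 104 in a fit to the compared groups alone. The authors' deposited table, which was chosen as an alternative only for the conditions against their primary cells, called 153 genes there. Against primary cholangiocytes (5087) it was 2806 with array weights, 1073 in a fit to the compared groups alone, and 2149 in the authors' deposited table. For primary cholangiocytes against undifferentiated cells (4955) it was 2290 with array weights and 1628 in a fit to the compared groups alone. The fits to the compared groups alone hold 5 to 7 arrays and so have fewer degrees of freedom, while the cause was not tested for the others. The difference of differences (9805) passed for 16988 genes with normexp background correction, and the cause was not tested.

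Leaving out 1 array at a time kept 60 of 68 counts within 1.5 times. The cholangiocyte condition against undifferentiated cells ranged from 128 to 396, the conditions against each other from 2641 to 3515, and primary cholangiocytes against undifferentiated cells from 3222 to 4450. Where a group was left with 1 array, that array was assumed to vary like the other groups.

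The replicate numbers were also taken as pairs, although over all groups the arrays that share a number were not alike on average (mean r of -0.002 over 28 pairs). Undifferentiated and cholangiocyte condition arrays of the same number were alike (0.281 to 0.385). Hepatocyte condition arrays matched undifferentiated arrays of mostly other numbers, and a block by that match was not fitted. Blocking by number gave 3597 genes for the hepatocyte condition against undifferentiated cells, 15170 and 4407 for the conditions against their primary cells, and 3531 between the conditions.

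The correlation of the lineage difference in culture with that in primary cells moved by less than its spread in all 23 alternatives and arrays left out. Movement of the cholangiocyte condition towards primary cholangiocytes, 0.073 in the values reported, was 0.020 with normexp background correction, and the cause was not tested. The other 3 movements stayed within their spread, computed the same way, in the 7 alternatives with all arrays.

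Of the list tests in the 8 comparisons of 2 groups, 96 passed with the preset correlation and 3 with the estimated one, which allows for lists whose members vary together. These were the interferon-stimulated genes in the hepatocyte condition against undifferentiated cells and against the cholangiocyte condition, and the biliary markers between the primary cell types. In the difference of differences the biliary markers also passed with the estimated one (adjusted p = 0.00977). Over the other alternatives 2407 of 2457 list tests kept their side of the threshold, 28 no longer passed and 22 newly passed. None that passed, before or after, turned in the direction camera gave, but medians near 0 changed sign for some lists, such as the biliary markers in the cholangiocyte condition against undifferentiated cells (0.01, and -0.13 with slide as a block). With 1 array left out 1392 of 1428 were kept, 24 no longer passed and 12 newly passed.

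Of the genes named, 2771 of 2782 values kept their side of the threshold over the alternatives, 5 no longer passed and 6 newly passed. None that passed, before or after, changed sign, but some that did not pass changed sign, such as C3 in the hepatocyte condition against primary hepatocytes (-1.33 to 0.15). With 1 array left out 1530 of 1549 were kept, 15 no longer passed and 4 newly passed. Signal over background limited dim genes: normexp correction with its offset made 46 of 189 differences that passed over 1.5 times smaller and ended no call.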

Other observations

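All tests in this part were chosen only after the results were seen.

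The secreted proteins that rose most in the hepatocyte condition, such as Lrg1, Fgb, Fgg and C4b, are made by liver cells in inflammation, so a list of 26 other acute-phase genes, sharing no gene with the fixed lists or the genes named by size, was tested as a hypothesis of an acute-phase response. Of these, 17 rose, none fell and 9 did not pass in the hepatocyte condition against undifferentiated cells, with a median of 3.88 (adjusted p = 2.48e-16 by camera of limma, adjusted over the comparisons of this list, and 0.000914 with an estimated correlation, n = 4 and 4). The receptor Osmr rose by 6.00 ± 0.39 (adjusted p = 5.47e-07), the siderophore-binding protein Lcn2 by 5.94 ± 1.12, the signalling inhibitor Socs3 by 4.17 ± 0.39 and the transcription factors Cebpd by 3.66 ± 0.32 and Stat3 by 1.59 ± 0.17. In the cholangiocyte condition none of the 26 passed and the median was -0.12 (adjusted p = 0.347). Between the conditions 18 were higher and 1 lower in the hepatocyte condition, with a median of 3.75 (adjusted p = 1.23e-17, and 0.000914 with an estimated correlation). Slide was not examined for this list. Against primary hepatocytes 9 of the 26 genes were higher and 7 lower, with a median of -0.34 (adjusted p = 0.289). These values are consistent with an acute-phase response in the hepatocyte condition (median 3.88), which is a hypothesis found and tested on the same arrays. The factors in the culture medium were not given in the sources used here, so a response to added cytokines or hormones, to the interferon signal or to differentiation itself cannot be separated.

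The 100 brightest probes held a mean of 20.4% of the intensity on primary hepatocyte arrays, 12.1% on those of undifferentiated cells, 13.6% and 12.9% on those of the hepatocyte and cholangiocyte conditions and 12% on those of primary cholangiocytes.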
